A study of Danio rerio with 8 samples.

How the data were processed

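Whole zebrafish embryos (Danio rerio) were measured in 8 pools, 4 from the control treatment and 4 from the BDE-209 treatment, per the labels, and each pool was hybridised to 1 array. Groups and replicate numbers were taken from the sample titles, which number the control pools 2, 3, 4 and 5 and the BDE-209 pools 1, 2, 3 and 5. Per the labels' protocols, total RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays, which were read on a GenePix scanner. Agilent Feature Extraction 9.5 is named in the submitters' processing notes. The series' design text names GeneSpring for the analysis and no test.

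The deposited scanner files of 7 arrays hold spot intensity on a linear scale. Per the file headers, the processed intensity of each spot had its background subtracted and was detrended within the array, with surrogate values for spots at background and no normalization between arrays. The deposited value table of the whole series holds the same intensity values, rounded, with a largest difference of 0.5 percent from the scanner files. Its scale is therefore linear, with no centring and no direction. Column medians of that table are 14.5, 12.1, 15.0 and 16.1 for control replicates 2, 3, 4 and 5, and 15.3, 14.4, 14.1 and 32.6 for BDE-209 replicates 1, 2, 3 and 5. The file of BDE-209 replicate 5 differs in kind from the other 7. It gives a spot number and 1 rounded signal per spot, equal to the value table, so no flags, background or slide of that array were used here. The slide of the other 7 arrays came from the file headers, and the probe coordinates are on build danRer5, per the file headers.

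From the deposited intensity, log2 of the processed signal was taken and the array's 75th percentile of it was subtracted. Control spots were left out, as were spots marked as outliers on the 7 arrays with flags. Spots of 1 probe were averaged. A probe was tested where it was well above background on at least 4 of the 7 arrays with flags, counted without regard to group. This rule had been written for 8 arrays, and 24842 of 43603 probes met it. Only 3 of the arrays with flags were of the BDE-209 group. A probe above background in the control pools alone could therefore be tested, and one above background in the BDE-209 pools alone could not. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), over all 8 arrays and without covariates, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. All log2 differences are BDE-209 minus control.

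Probes were named through the current gene tables. Of the 43603 probes, 16075 were named by accession, 2532 by gene number, 1046 by a current symbol, 1446 by a synonym and 46 by an Ensembl match, and 22458 kept the name in the files. An informative symbol, not a clone or locus placeholder, was held by 19768 probes of 13345 genes. The pattern that finds placeholders was corrected once after values had been seen, because it took nr4a1 for a clone name. Where a gene had several probes, the probe with the highest mean signal among those tested stood for it.

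The genes named in the text follow a fixed rule. In each direction it takes up to 10 genes with an informative symbol, the largest changes past the threshold with no overlap of the groups. Where fewer than 10 passed, it adds the genes of smallest unadjusted p without overlap, which are called not significant. It also takes up to 4 members of each gene list discussed, by smallest unadjusted p, and a fixed set of genes of detoxification, stress, the thyroid axis, myelin, cholinergic signalling and vitellogenin. Further genes are named only where the text says that they were chosen after their values were seen.

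The 35 gene lists, with 1491 entries of which 1226 are on the array, cover detoxification, endocrine axes, stress, metabolism, the nervous system and the tissues of an embryo. They were tested with limma's camera at a preset correlation between genes of 0.01, with 1 probe per gene and adjustment over the 35 lists. Camera with an estimated correlation and fry were run beside it. The median of each list was also ranked among 10000 random lists of genes matched on mean signal, which ignores correlation between genes. Members were also counted after adjustment over the list alone. Chosen after the data were seen, an exact permutation test compared the median of each list per array between the groups. Array quality was compared by exact permutation tests. The whole profile was compared as the mean correlation distance between groups minus that within groups, by an exact permutation over all 35 splits of the arrays into 4 and 4. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

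The fit was tested on simulated data for the comparison of BDE-209 with control, over 24630 probes with the real means and spreads, with 200 changed probes in each of 10 runs. Of the changed probes, limma recovered 4.4 percent at a log2 difference of 0.5, 61.8 percent at 1, 88.4 percent at 1.5 and 94.4 percent at 2, with no call in the wrong direction. It called 0.0254 percent of the unchanged probes. Camera called all 10 lists shifted by 0.3 and 0 of 340 unshifted ones, but the simulated noise was independent between genes, so this does not test the preset correlation.

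The tests, the rule for named genes, the lists and the first set of alternatives were chosen before the data were examined. Those alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50 on the mean and background intensity followed by quantile normalization, the value table, no filter on dim probes, a filter on all 7 arrays with flags, outlier spots kept, each array left out, the replicate number and the slide as blocks, array weights, a trended robust prior, no moderation, and averaging the probes of a gene. The normexp fit covers the 7 arrays with background values. Added after the data were seen were the slide as a random block, quantile normalization without BDE-209 replicate 5, and a fit to probes above the median signal.

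The number of arrays limits the precision. Each value rests on pools, and nothing in the labels says how the pools were drawn, so p-values measure only the spread between these pools, which may in part be technical.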

Results

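Gene expression was profiled in whole zebrafish embryos from sediment dosed with BDE-209 and from a control treatment. BDE-209 is decabromodiphenyl ether, a fully brominated flame retardant that binds to sediment, and the dose given in the labels was 12500 ng per g of sediment. The study asked whether embryos exposed through sediment differ from controls. Each group had 4 pools of embryos, with 1 array per pool. Between 23089 and 26762 probes per array were well above background on the 7 arrays with flags, and the 75th percentile of the signal lay between 98.5 and 136. None of 7 measures of array quality differed between the groups in exact permutation tests, with p from 0.143 to 0.914. The array of BDE-209 replicate 5 stood apart, with a median signal of 33.7 against 12.9 to 17.1 on the other arrays.

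Among the 9 named genes that were higher in the BDE-209 pools were several that encode transcription factors. fosab, a subunit of the AP-1 transcription factor, was higher by 1.78 ± 0.21 on the log2 scale (SE, n = 4 per group, 3.43-fold, limma adjusted p = 0.0267). junbb, another AP-1 subunit, was higher by 1.13 ± 0.12 (adjusted p = 0.0132), and jdp2b, which pairs with Jun proteins, by 1.69 ± 0.15 (adjusted p = 0.0114). npas4a, a transcription factor of active neurons, was higher by 1.71 ± 0.19 (adjusted p = 0.0202), and nr4a1, an orphan nuclear receptor, by 1.304 ± 0.16 (adjusted p = 0.03). btg2, which restrains cell division, rose by 1.48 ± 0.12 (adjusted p = 0.0109), and ccn1, a secreted matrix protein, by 1.49 ± 0.15 (adjusted p = 0.0132). adamts1, a secreted protease, rose by 1.80 ± 0.22 (adjusted p = 0.0303), although its probe was well above background on 3 of the 4 control arrays. f3b, a tissue factor that starts blood clotting, rose by 1.52 ± 0.18 (adjusted p = 0.025).

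The largest change was a fall. fkbp5, a co-chaperone whose transcription is driven by the glucocorticoid receptor, fell by 2.18 ± 0.24 on the log2 scale (SE, n = 4 per group, 4.54-fold, limma adjusted p = 0.0193), from a normalised signal of 3.25 ± 0.41 (SD, n = 4) to 1.07 ± 0.35 (SD, n = 4). Its second probe fell by 2.39. inhbb, which encodes the activin beta B subunit, fell by 1.52 ± 0.14 (adjusted p = 0.0126). pfkfb4b, a regulator of glycolysis, fell, at -1.16 ± 0.15 (adjusted p = 0.042), as did pik3r3a, a regulatory subunit of phosphoinositide 3-kinase, at -1.16 ± 0.12 (adjusted p = 0.0132). stra6, a membrane transporter of retinol, fell, at -0.91 ± 0.11 (adjusted p = 0.03). Of several probes of inhbb, pfkfb4b and stra6, 1 each passed, and the others differed in the same direction, the weakest at -1.14, -0.95 and -0.22. The genes next in line did not pass the test. klhl43 was higher by 0.87 (adjusted p = 0.0504). abracl was lower by a difference of -0.71, rgrb and opn1lw1, both of the retina, by -0.92 and -0.89, abcf2a by -0.97 and tm6sf2b by -0.94, with adjusted p from 0.0668 to 0.137.

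**Figure D1:**
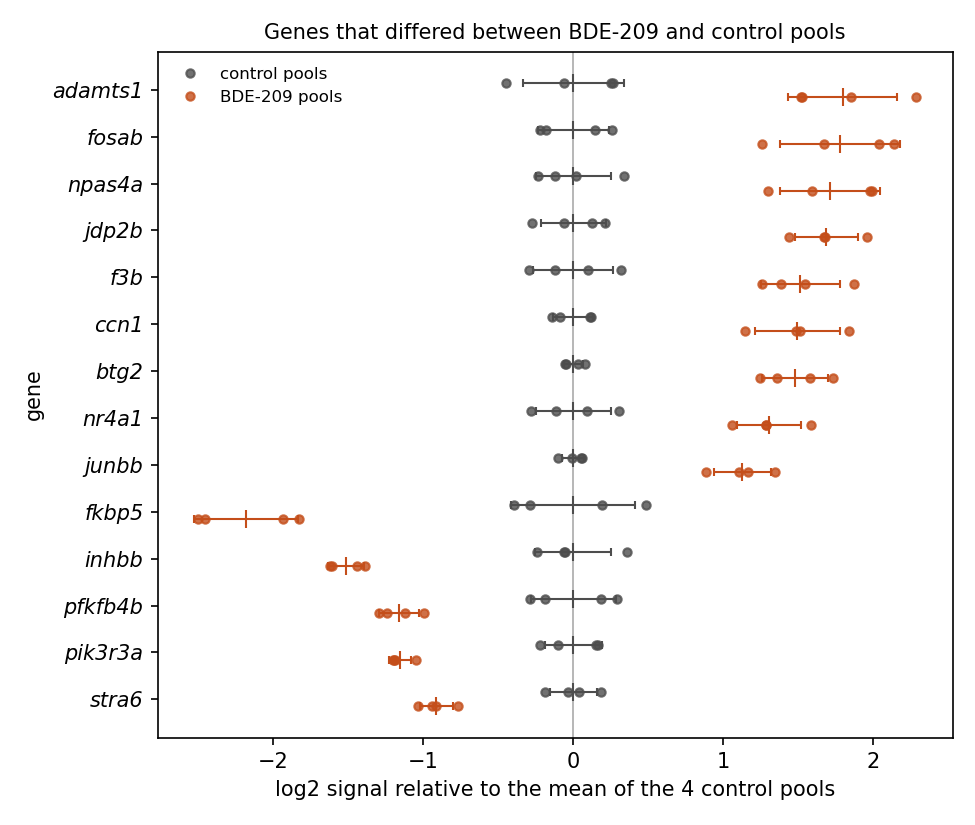
Log2 signal per pool, relative to the mean of the 4 control pools, of the 14 named genes past the threshold, with points for pools, ticks for group means and bars for the SD (n = 4). For each gene all 4 BDE-209 pools lie on 1 side of all 4 control pools, from fkbp5 at -2.18 to adamts1 at 1.80.

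On the genome build of the array design, danRer5, the probe of fosab (A_15_P141001) lies on chromosome 20 at 46831309 to 46831368, and that of jdp2b, close by on the same chromosome, at 46873448 to 46873507. The probe of fkbp5 (A_15_P100902) lies on chromosome 6 at 27969282 to 27969341 and that of pfkfb4b on the same chromosome at 39658747 to 39658806. The probe of npas4a lies on chromosome 14 at 27599936 to 27599995, that of inhbb on chromosome 9 at 31151677 to 31151736 and that of stra6 on chromosome 25 at 18886097 to 18886156. Which exon or untranslated region each covers was not analysed here.

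In all, 29 of 24842 probes passed, 22 higher and 7 lower, and none of the 29 had overlapping groups. They stand for 17 names higher and 6 lower, of which 9 and 5 are informative gene symbols. Of the 5 fosab probes, 4 passed, with differences over the 5 from 1.65 to 2.01, and both probes of ccn1, f3b and fkbp5 passed. Among the probes without an informative symbol, EF583630, described in the files as the small heat shock protein HSPB9, rose by 1.66 ± 0.14 (adjusted p = 0.0109). LOC566268, described as similar to a regulator of G-protein signalling, rose by 1.58 ± 0.17 (adjusted p = 0.0193). These 2 were chosen after their values were seen. At an unadjusted p under 0.05 there were 1243 probes higher and 1329 lower, 2572 against 1242 by chance, and 649 of these differed by at least 1.5-fold. Over the other splits of the 8 arrays into 4 and 4, the count at that unadjusted p ran from 466 to 1840. Groups did not overlap for 8.29% of the probes, against 2.86% by chance.

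Slides 1, 2 and 3 each held 1 array of each group, and the 20 genes named above differed in the same direction on all 3. That sameness of direction was fixed in advance, since these genes were chosen for no overlap of the groups. They were also chosen by large differences or small p over arrays that include these. The sizes, and the share of them kept with a slide block, were thus largely fixed too and are given only as description. Within slides 1, 2 and 3, fosab differed by 1.78, 1.53 and 2.32, junbb by 1.11, 1.29 and 1.27, inhbb by -1.55, -1.80 and -1.38, and fkbp5 by -2.65, -2.32 and -1.65. With the slide as a block over those 6 arrays the difference was 1.88 for fosab, 1.22 for junbb, -1.58 for inhbb and -2.21 for fkbp5. The 20 genes kept between 84.5% and 109% of their differences, but limma called 0 probes with the block, at 1470 higher and 931 lower by unadjusted p, and the adjusted p of the 20 genes lay between 0.441 and 0.502. The count was also 0 without moderation of the variances (1093 higher and 1673 lower by unadjusted p) and without the filter on dim probes (1890 and 1021). It was 19 without control replicate 3, 1 without control replicate 4, 5 without control replicate 5, 8 without BDE-209 replicate 1, 3 without BDE-209 replicate 2, and 0 without BDE-209 replicate 3 (limma; 1710 and 1222 by unadjusted p). Without BDE-209 replicate 5 it was 22, of which 20 were shared. Median scaling gave 21 higher and 24 lower beside the 22 and 7, with 17 probes shared, and moved the median of all probes to -0.28 from -0.002. Under normexp with quantile normalization over 7 arrays, 3 genes shrank by more than 1.5 times, adamts1 to 0.317 (adjusted p = 0.127), f3b to 0.375 (0.0832) and inhbb to -0.867 (0.00924), and stra6 shrank to -0.562 (0.228) when the probes of a gene were averaged. Over all alternatives the adjusted p ran from 0.0064 to 0.441 for adamts1, from 0.0109 to 0.544 for f3b, from 0.000279 to 0.464 for inhbb and from 0.00466 to 0.552 for stra6. adamts1 passed in none of the 8 fits that left out 1 array, with adjusted p from 0.0554 to 0.145.

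Gene lists fixed in advance showed shifts spread over many genes, most of them small. Of 35 lists, 14 passed camera at the preset correlation, 4 higher and 10 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.29. fry called 4 of the lists, all lower. Per pool, medians were taken of signals relative to the mean of all 8 arrays. In 7 lists the 4 BDE-209 pools and the 4 control pools did not overlap, at p = 0.0286, the smallest that the exact permutation test of 4 against 4 can give, and adjusted over the 35 lists no p was under 0.143. Relative to the mean of the controls, as drawn in the figure of lists, 3 of these 7 did overlap, namely hypoxia and glycolysis, calcium handling, and cartilage and bone. The count of lists was 6 without BDE-209 replicate 2, 8 under quantile normalization and 9 with normexp and quantile normalization. With the slide as a block it was 13, of which 11 were shared. Of the 14 lists, cell proliferation, retina phototransduction, muscle, oxidative phosphorylation and cholesterol biosynthesis passed whichever array was left out.

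Genes of the cell cycle were lower as a group. The median difference over the 48 measured members of the cell proliferation list was -0.40, with 46 of the 48 below 0 (camera adjusted p = 8.88e-19, and adjusted p = 0.351 with an estimated correlation). Of these members 10 fell and 0 rose by limma adjusted over the list alone, and 0 over all probes. They include cdk1, the kinase that drives mitosis, at -0.60 ± 0.12 (SE, n = 4), the mitotic motor kif11 at -0.80 ± 0.16, the checkpoint protein bub3 at -0.41 ± 0.09 and the histone chaperone chaf1a at -0.47 ± 0.10 (the weakest of its 3 probes at -0.18). The median was -0.33 with the slide as a block, and -0.10, -0.28 and -0.58 within slides 1, 2 and 3. Under normexp with quantile normalization it halved to -0.198, and cdk1 shrank to -0.361. With the probes of a gene averaged chaf1a was at -0.285. Per pool the groups overlapped, with exact permutation p = 0.0571.

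Genes of the retina were lower too. Over 52 measured members of the retina phototransduction list the median difference was -0.29, with 44 below 0 (camera adjusted p = 1.41e-12, and adjusted p = 0.29 with an estimated correlation). By limma adjusted over the list alone 18 fell and 1 rose. opn1lw1, a red cone opsin, fell, at -0.89 ± 0.15 (SE, n = 4), as did rgrb, a retinal G-protein coupled receptor, at -0.92 ± 0.15, the retinaldehyde-binding protein rlbp1b at -0.80 ± 0.15 and the cone transducin subunit gngt2a at -0.76 ± 0.16. rgrb and rlbp1b belong to the pigment epithelium and glia that serve the photoreceptors. The 1 that rose was guca1g, a guanylate cyclase activator, at 0.43 ± 0.10 (0.28 under normexp with quantile normalization), chosen after its value was seen. This list passed fry as well (adjusted p = 0.0147), and its per-pool medians did not overlap between groups (exact permutation p = 0.0286). The median was -0.25 with the slide as a block, -0.15 under normexp with quantile normalization, and -0.23, -0.23 and -0.21 within slides 1, 2 and 3.

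Contractile proteins of skeletal muscle were higher. The median over 31 measured members was 0.37, with 28 above 0 (camera adjusted p = 1.17e-10, and adjusted p = 0.351 with an estimated correlation). By limma adjusted over the list alone 13 rose and 1 fell. actc1b, a muscle actin, rose by 0.81 ± 0.14 (SE, n = 4), myoz1a, a protein of the sarcomere's Z-disc, by 0.83 ± 0.16, ldb3b, another Z-disc protein, by 0.82 ± 0.16 and the muscle aldolase aldoab by 0.69 ± 0.16. mb, the oxygen store myoglobin, fell, at -0.90 ± 0.20, and was chosen after its value was seen. The median was 0.32 with the slide as a block and 0.18, 0.35 and 0.40 within slides 1, 2 and 3, and the groups did not overlap (exact permutation p = 0.0286). In the calcium handling list of 20 measured members, which did not pass camera (adjusted p = 0.0519, median 0.17), 4 rose and 2 fell by limma adjusted over the list alone. jph2, which ties the muscle membrane to its calcium store, rose by 0.86 ± 0.14, the release channel ryr3 by 0.47 ± 0.10 and the calcium pump atp2a1l by 0.76 ± 0.17, while the pump atp2a2b fell, at -0.62 ± 0.12. Under normexp with quantile normalization ldb3b shrank to 0.413 and atp2a2b to -0.193. Heart genes had a median of 0.09 over 13 members and did not pass (camera adjusted p = 0.0664).

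**Figure D2:**
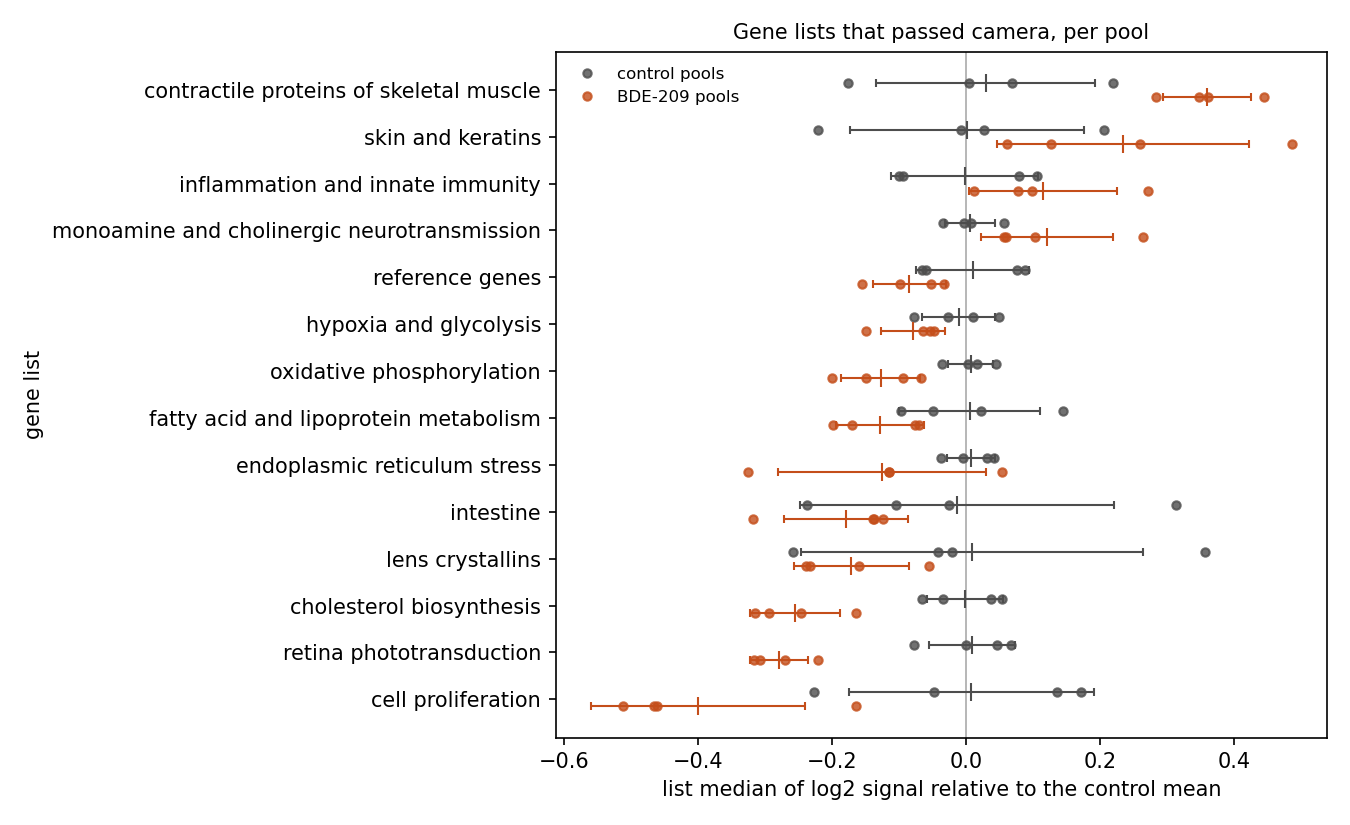
Median over each gene list of the log2 signal relative to the mean of the 4 control pools, for the 14 lists that passed camera at the preset correlation, with points for pools, ticks for group means and bars for the SD (n = 4). Retina phototransduction shows no overlap of the groups, whereas in cell proliferation BDE-209 replicate 1 at -0.16 lies above control replicate 3 at -0.23.

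Metabolic genes were lower by smaller amounts. Oxidative phosphorylation had a median of -0.14 over 70 members, 61 of them below 0 (camera adjusted p = 2.32e-07, and adjusted p = 0.351 with an estimated correlation; fry adjusted p = 0.0456), with 0 members past limma adjusted over the list alone and 8 by unadjusted p. Its subunit cox7b differed by -0.30 ± 0.09 (SE, n = 4). Cholesterol biosynthesis had a median of -0.26 over 21 members (camera adjusted p = 2.24e-05, and adjusted p = 0.351 with an estimated correlation), with 0 members past limma adjusted over the list alone and 9 by unadjusted p. Its enzymes idi1 and hmgcs1 differed by -0.49 ± 0.12 and -0.38 ± 0.13, and over all alternatives their weakest differences were -0.234 and -0.264. Hypoxia and glycolysis had a median of -0.08 over 40 members (camera adjusted p = 0.013, and adjusted p = 0.351 with an estimated correlation). In it 1 rose and 5 fell by limma adjusted over the list alone, gpib by 0.71 ± 0.12 upwards, and pfkfb4b, tfa at -0.62 ± 0.14 (the weakest of its 6 probes at -0.01) and pgam1a at -0.45 ± 0.10 downwards. gpib and pgam1a encode glycolytic enzymes and tfa the iron carrier transferrin. Fatty acid and lipoprotein metabolism had a median of -0.14 over 49 members (camera adjusted p = 0.013, and adjusted p = 0.526 with an estimated correlation), with 0 members past limma adjusted over the list alone, 12 by unadjusted p, and fabp7a at -0.43 ± 0.10. Exact permutation p per pool was 0.0286 for oxidative phosphorylation, cholesterol biosynthesis and hypoxia, and 0.2 for fatty acid metabolism. Relative to the mean of the controls the hypoxia groups overlapped, with control replicate 3 at -0.078 below BDE-209 replicates 1, 2 and 3 at -0.054, -0.065 and -0.048. Of the random lists matched on mean signal, 14.7 percent had a median below that of hypoxia, which was thus not unusual for genes of that brightness. The share was 0.8 percent for oxidative phosphorylation and 0 for cholesterol and for fatty acid metabolism. Normexp with quantile normalization shrank the medians to -0.043 for oxidative phosphorylation, -0.083 for cholesterol, -0.047 for hypoxia and -0.084 for fatty acid metabolism, and gpib to 0.384. With the slide as a block the medians were -0.13, -0.21, -0.10 and -0.16 in the same order. Within slides 1, 2 and 3 they were -0.12, -0.09 and -0.15 for oxidative phosphorylation, -0.11, -0.18 and -0.17 for cholesterol, -0.08, -0.05 and -0.12 for hypoxia, and -0.20, -0.02 and -0.12 for fatty acid metabolism. Quantile normalization ended the camera calls of oxidative phosphorylation (median -0.062, adjusted p = 0.142), hypoxia (0.314) and fatty acid metabolism (0.142). The hypoxia call was lost without BDE-209 replicate 2 (adjusted p = 0.0609), and its median shrank to -0.055 without BDE-209 replicate 5. That of fatty acid metabolism was lost without control replicate 2 (median -0.087, adjusted p = 0.0762), BDE-209 replicate 1 (0.172) or BDE-209 replicate 2 (median -0.095, 0.0609). The replicate number as a block ended both calls (0.126 for hypoxia, 0.262 for fatty acid metabolism with a median of -0.09), as did a fit to probes above the median signal (0.0963 and 0.184). Hypoxia was also lost under median scaling (0.0853) and under quantile normalization without BDE-209 replicate 5 (median -0.047, 0.0626), where oxidative phosphorylation kept its call at a median of -0.078. Without a filter on dim probes the medians of hypoxia and fatty acid metabolism were -0.052 and -0.072.

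Lens, skin and intestine lists also passed camera. Lens crystallins had a median of -0.23 over 28 members (camera adjusted p = 0.00509, and adjusted p = 0.602 with an estimated correlation), with crygm2b at -1.003 ± 0.30 (SE, n = 4). The intestine list had a median of -0.23 over 24 members (camera adjusted p = 0.0388, and adjusted p = 0.526 with an estimated correlation). Skin and keratins had a median of 0.25 over 30 members (camera adjusted p = 0.00715, and adjusted p = 0.526 with an estimated correlation), with anxa1a at 0.70 ± 0.16. In these 3 lists 0 members passed limma adjusted over the list alone, and 2, 4 and 3 did by unadjusted p. Exact permutation p per pool was 0.4, 0.314 and 0.171. The slide-block medians were -0.29, -0.33 and 0.22. Within slides 1, 2 and 3 the medians were -0.27, -0.56 and -0.02 for the lens, -0.53, 0.15 and -0.18 for the intestine, and 0.22, 0.01 and 0.20 for the skin. The lens call was lost without control replicate 3 (median -0.105, adjusted p = 0.337) or BDE-209 replicate 1 (0.0654), and the skin call without control replicate 5 (0.1) or BDE-209 replicate 2 (median 0.163, 0.0809). The intestine call was lost without control replicate 2 (median -0.119, 0.294), BDE-209 replicate 1 (median -0.143, 0.267) or BDE-209 replicate 2 (0.0886). Quantile normalization ended the lens call (0.124), and normexp with quantile normalization the skin call (0.0611). The latter shrank the 3 medians to -0.123, -0.127 and 0.107, and without a filter on dim probes the intestine median was -0.093 and the skin call was lost (0.0729). The intestine call was also lost with array weights (0.0776), a filter on all 7 arrays with flags (0.0776) and the replicate number as a block (0.262). A fit to probes above the median signal ended the lens (0.287) and intestine (0.368) calls.

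The remaining calls were those of inflammation and innate immunity (median 0.14 over 36 members, camera adjusted p = 0.0172, and adjusted p = 0.526 with an estimated correlation) and of monoamine and cholinergic neurotransmission (0.07 over 24, 0.0372, and adjusted p = 0.526 with an estimated correlation). Endoplasmic reticulum stress (-0.15 over 31, camera adjusted p = 0.0416, and adjusted p = 0.69 with an estimated correlation) and reference genes (-0.08 over 20, 0.046, and adjusted p = 0.526 with an estimated correlation) were the other two. By limma adjusted over the list alone, socs3a, a brake on cytokine signalling, rose by 1.41 ± 0.25 (SE, n = 4) in the first. nr4a2b and chrna1, a subunit of the muscle acetylcholine receptor, rose by 0.55 ± 0.13 and 0.48 ± 0.12 in the second, and the transcription factor atf3 rose by 0.74 ± 0.12 in the third, against the median of its list. actb1 and tubb4b, cytoskeletal genes often used for scaling, fell, at -0.38 ± 0.09 and -0.37 ± 0.09. With the slide as a block the medians were 0.11, 0.17, -0.07 and -0.09 and 3 of the 4 calls were lost, that of monoamine and cholinergic neurotransmission being kept (adjusted p = 0.015). Within slides 1, 2 and 3 they were 0.001, -0.03 and 0.32 for inflammation, 0.14, 0.11 and 0.39 for monoamine and cholinergic neurotransmission, 0, -0.10 and -0.06 for endoplasmic reticulum stress, and -0.13, -0.10 and -0.11 for reference genes. Exact permutation p per pool lay at 0.314, 0.0857, 0.143 and 0.0857. Of the random lists matched on mean signal, 99.9, 72, 0.4 and 46.6 percent had a lower median, in the same order. The medians of monoamine and cholinergic neurotransmission and of reference genes were thus not unusual for genes of that brightness. Without BDE-209 replicate 5 the adjusted p was 0.136 for inflammation, 0.271 for endoplasmic reticulum stress and 0.117 for reference genes, and without BDE-209 replicate 2 it was 0.129, 0.18, 0.0823 and 0.0823 for the 4 lists in the order named. Inflammation was also lost without control replicate 4 (median 0.09, adjusted p = 0.062) or 5 (0.0517). Monoamine and cholinergic neurotransmission was lost without control replicate 2 (0.0761), control replicate 4 (0.0623) or BDE-209 replicate 3 (0.073). Endoplasmic reticulum stress was lost without control replicate 2 (0.0761), 4 (0.0585) or 5 (0.0692), and reference genes without control replicate 2 (0.0904), control replicate 3 (0.141) or BDE-209 replicate 1 (0.114). Quantile normalization ended all 4 calls, at adjusted p of 0.0557, 0.165, 0.483 and 0.461, as did normexp with quantile normalization, at 0.118, 0.0965, 0.408 and 0.163. The latter shrank the 4 medians to 0.036, 0.026, -0.069 and -0.02. The monoamine and cholinergic median lay at 0.039 without control replicate 2, 0.041 without BDE-209 replicate 2, 0.1 without control replicate 3 or 5, and 0.103 without BDE-209 replicate 5. Without a filter on dim probes inflammation (median 0.213, adjusted p = 0.051) and monoamine and cholinergic neurotransmission (0.16, 0.191) were lost. Endoplasmic reticulum stress and reference genes were lost with array weights (medians -0.093 and -0.052, adjusted p = 0.0659 and 0.205) and with a filter on all 7 arrays with flags (0.0745 and 0.0788), and reference genes with the replicate number as a block (0.126). Median scaling ended the calls of monoamine and cholinergic neurotransmission (0.0951), endoplasmic reticulum stress (0.0957) and reference genes (0.199), and a fit to probes above the median signal ended the same 3 (0.287, 0.298 and 0.351) and put the inflammation median at 0.075. Quantile normalization without BDE-209 replicate 5 ended inflammation (0.13), endoplasmic reticulum stress (median -0.072, 0.593) and reference genes (0.105). With array weights the monoamine and cholinergic median was 0.104, and under quantile normalization the medians of inflammation, endoplasmic reticulum stress and reference genes were 0.048, -0.096 and -0.048.

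The glucocorticoid and stress axis moved in both directions. As a list of 22 members it did not pass camera (median -0.05, adjusted p = 0.975), whereas fry's test for change in either direction did (adjusted p = 4.49e-08), as it did for 20 of the 35 lists. By limma adjusted over the list alone 3 rose and 2 fell. cebpb, a transcription factor, rose by 0.90 ± 0.13 (SE, n = 4), the phosphatase dusp1 by 0.62 ± 0.12 (its second probe by 0.28) and the kinase sgk1 by 0.30 ± 0.09, while fkbp5 and avp, the vasopressin precursor, fell, avp at -0.46 ± 0.10. sgk1 was chosen after its value was seen. In the circadian clock list of 34 members (median 0.05, camera adjusted p = 0.596), bhlhe40 rose by 0.76 ± 0.13 and nr1d2a fell, at -1.499 ± 0.34, by limma adjusted over the list alone. The second probe of nr1d2a differed by -0.14 and was well above background on 3 of 4 control arrays and 1 of 3 BDE-209 arrays with flags. In the p53 and apoptosis list of 29 members (median 0.03, camera adjusted p = 0.359), gadd45bb and gadd45ab, both growth arrest genes, rose by 1.11 ± 0.15 and 0.61 ± 0.14 by the same count. Under normexp with quantile normalization gadd45bb shrank to 0.396, and with the probes of a gene averaged nr1d2a shrank to -0.818.

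Targets and axes often examined for brominated flame retardants did not pass camera as groups. The aryl hydrocarbon receptor list (13 members, median 0.16, camera adjusted p = 0.272) and the thyroid axis list (19 members, median -0.08, adjusted p = 0.684) had 0 members past limma adjusted over the list alone, and 1 each by unadjusted p. fry's test for change in either direction passed for the first (adjusted p = 0.00886) and not for the second (0.429). cyp1a, the classic marker of that receptor, differed by 0.16 ± 0.14 (SE, n = 4, limma adjusted p = 0.729), ahrra by 0.29 ± 0.17 (0.581) and tiparp by 0.46 ± 0.14 (0.316), with its second probe at -0.05. The deiodinases dio1 and dio2 differed by 0.30 ± 0.17 and 0.33 ± 0.17, the thyroid hormone receptors thraa and thrb by -0.19 ± 0.15 and 0.03 ± 0.10, and the hormone carrier ttr by -0.08 ± 0.35. Within slides 1, 2 and 3 cyp1a differed by -0.13, 0.19 and 0.26, dio1 by -0.18, 0.66 and 0.15, and ttr by -1.41, 0.90 and 0.22. cyp3a65, a drug-metabolising enzyme, differed by -0.37 ± 0.33, hsp70l, a heat shock protein, by -0.01 ± 0.19, mbpa, a myelin protein, by 0.25 ± 0.13 and ache, which breaks down acetylcholine, by 0.31 ± 0.11, and none of these passed. tg, tshba and vtg1 were not well above background on enough arrays, and tpo and dio3b were not measured here. Direction was not settled for hsp70l, which was above 0 under quantile normalization at 0.05.

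The remaining lists did not pass camera. Other drug-metabolising enzymes had a median of -0.03 (27 members, camera adjusted p = 0.596), oxidative stress -0.07 (27, 0.382) and heat shock and protein folding 0.03 (27, 0.684). Neuronal development and glia had a median of -0.04 (35, 0.257), GABA and glutamate neurotransmission 0.004 (31, 0.684) and oestrogen response 0.14 (7, 0.596). Among tissues, cartilage and bone had a median of -0.07 (30, 0.151), the hatching gland -0.14 (10, 0.0516), the liver -0.03 (36, 0.684), the pancreas -0.01 (25, 0.661) and germ cells 0.02 (8, 0.684). Ribosomal proteins had a median of -0.03 (78, 0.395). Red blood cells had a median of -0.04 (22, 0.409), with the globin hbae1.1 lower by limma adjusted over the list alone, at -0.52 ± 0.12 (SE, n = 4). Ionocytes had a median of -0.10 (17, 0.983), with the ammonia transporter rhcga higher by 1.56 ± 0.28 and nherf1a lower at -0.34 ± 0.09 by the same count. nherf1a was not written in this list and entered it through the matching of gene synonyms. The files name its probe slc9a3r2, so its difference is not that of a gene chosen for ionocytes. In germ cells zp2.2 was lower by that count, at -0.42 ± 0.11, while its second probe was at 0.24. Under normexp with quantile normalization rhcga shrank to 0.274, nherf1a to -0.154 and zp2.2 to -0.157, and zp2.2 was at -0.086 with the probes of a gene averaged. For the pancreas, liver and glucocorticoid lists camera's direction was opposite in sign to the median. The ionocyte list had a mean of 0.10, opposite to its median and to camera's direction.

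Taken as whole profiles the groups differed by a small margin, and the control arrays were more alike than the BDE-209 arrays. Correlations between arrays over the tested probes lay between 0.958 and 0.993. Control arrays correlated with each other at 0.9817 to 0.9935. BDE-209 arrays correlated with each other at 0.9615 to 0.9806 and with control arrays at 0.9584 to 0.9876. The BDE-209 arrays were thus no more alike among themselves than they were to the controls. The mean distance between groups exceeded that within groups by 0.00171, the highest of the 35 splits (exact permutation p = 0.0286, one-sided, the smallest this design can give). Without BDE-209 replicate 5 the excess was 0.00246 with p = 0.0571, and without BDE-209 replicate 2 it was 0.00424 with p = 0.0571 (exact permutation). Without control replicate 2, 3, 4 or 5 it was below 0, at -0.000808, -0.000652, -0.000577 and -0.000656, with exact permutation p from 0.6 to 0.629. All pairs within groups were pooled, so leaving out an array of 1 group gives the other group more weight in the within-group mean. The sign and size of these leave-out values in part reflect that weight, so they do not show which arrays the margin rests on. Under normexp with quantile normalization over 7 arrays the excess was 0.00192, and without a filter on dim probes 0.00114, each with exact permutation p = 0.171. No value with the slide as a block was computed for this measure.

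**Figure D3:**
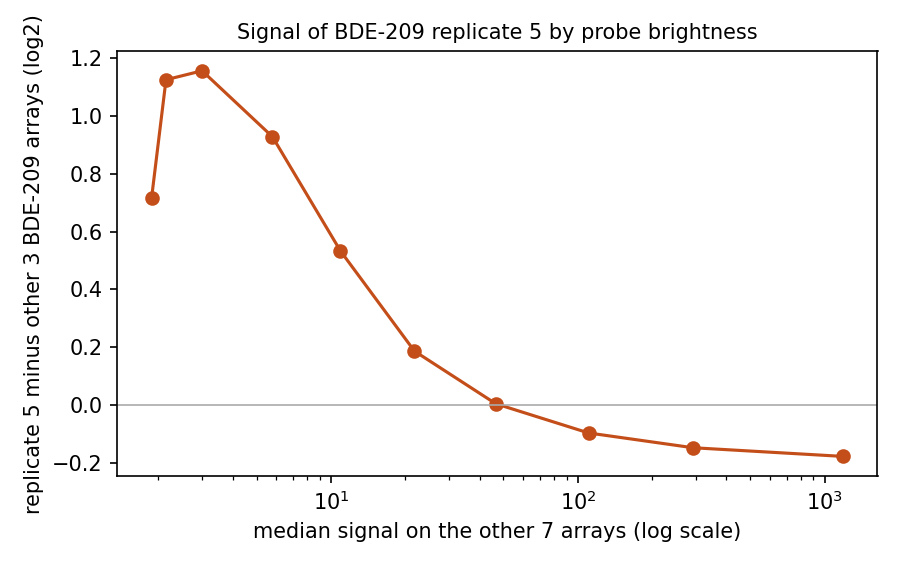
Median log2 difference, after scaling to the 75th percentile, between BDE-209 replicate 5 and the mean of the other 3 BDE-209 arrays, for probes in 10 groups of rising brightness, against the median signal on the other 7 arrays on a log axis. The difference is 1.16 among dim probes of median signal 3.01 and -0.18 among the brightest.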

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

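The tests of BDE-209 replicate 5 as a cause, of what set that array apart, and of a later stage were chosen only after the result was seen.

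In groups of 4 arrays, a value was singled out where its gap to the nearest other array exceeded the share of the group's range set by Dixon's test for 4 values, and chance flags about 1 in 20 groups. This held for 15 of 235 groups, 7 of 186 for genes, 3 of 28 for gene lists and 5 of 21 for array measures. On the array of BDE-209 replicate 5 the median signal was 33.7, with 16.16 the nearest in its group, the dim spike-in was at 28.5 against 2.26 and the low spike-in at 56 against 8.24. For BDE-209 replicate 1 the bright spike-in lay 7.023 above the 75th percentile on the log2 scale, against 6.841. For control replicate 2 the spread between repeated spots was 18.5 percent, against 8.5. In normalised log2 signal, klhl43 was at -0.71 in control replicate 5 against -0.465, pik3r3a at 1.123 in BDE-209 replicate 3 against 0.985, and ldb3b at 0.175 in BDE-209 replicate 2 against 0.001. thraa was at -0.619 in control replicate 3 against -0.852, actb1 at 7.329 in control replicate 2 against 7.227, anxa1a at 2.573 in BDE-209 replicate 2 against 2.03, and opn1mw1 at 8.028 in control replicate 5 against 7.872. Among list medians relative to the control mean, cell proliferation was at -0.164 in BDE-209 replicate 1 against -0.461, hypoxia and glycolysis at -0.15 in BDE-209 replicate 5 against -0.065, and intestine at -0.318 in BDE-209 replicate 1 against -0.139.

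The array of BDE-209 replicate 5 was brighter than the others on dim probes. Its negative controls, at 2.22 against at most 2.08 elsewhere, exceeded those of the other arrays by 0.528 percent of the excess of the dim spike-in, which argues against an equal offset on every spot. The dim spike-in, which binds no fish RNA, was 12.6-fold over the highest of the other arrays, so a different RNA content of the pool cannot be the whole cause. For added signal on dim probes, 3 of 3 dim spike-in probes were higher than on any other array, but so was 1 of 5 bright ones, which lies near saturation, and this explanation stays open. Beyond the pool's RNA content no biological explanation was tested.

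fosab, junbb and npas4a were among the probes called higher in the BDE-209 pools, and no list of genes of their kind was fixed or tested. Over the 7 arrays without BDE-209 replicate 5 all probes called higher together kept 103 percent of their median difference. These probes were chosen with that array included, for a small spread within groups, and their groups did not overlap. Such a share was thus largely fixed in advance and decides nothing about that array as the cause. In the fit without that array limma called 22 probes, 16 higher and 6 lower. Of these, 20 in both directions together were also called with it, so those 20 calls did not rest on that array. Groups collected at different times of day would move clock genes, and 2 circadian clock genes passed adjusted over the list alone, bhlhe40 and nr1d2a, where at least 3 had been set for and 0 against, and the second probe of nr1d2a differed by only -0.136, so this stays open. Handling at collection may also differ between the groups and was not tested. Exposure to BDE-209 stays open as well, since these data cannot separate it from how the groups were kept and collected.

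Genes of the retina phototransduction list were lower in the BDE-209 pools. A smaller share of the whole retina would lower genes of its other neurons and progenitors as well, but over 23 measured ones, some also used in the brain, the median difference was -0.021. Its standard error of 0.06 was taken over genes as if they were independent, and does not measure the spread between pools. Per pool the difference was -0.025 (exact permutation p = 0.714). These values argue against a smaller share of the whole retina. That set held no genes of pigment epithelium or glia, of which rgrb, rlbp1b and rpe65a, the last chosen after its value was seen, were at -0.92, -0.796 and -0.757 and passed as lower over the list alone, so a smaller share of photoreceptors with these cells stays open. Without BDE-209 replicate 5 the photoreceptor median was -0.305, which argues against that array. A later stage was examined only through these genes themselves, whose median of -0.286 is the pattern, so it decides nothing. Stage, earlier or later, and the exposure itself stay open.

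Of the 35 splits of the 8 arrays into 4 and 4, only the real 1 gave as many changed probes as the real 29, the highest other being 3. A share of 1 in 35 is the smallest that this design can give, so chance is made less likely for that count but is not excluded. The splits do not hold the slides fixed, and with the slide as a block over 6 arrays limma called 0 probes (1470 higher and 931 lower by unadjusted p). For gene lists, 2 of the 35 splits gave at least the real 14, the highest other being 15 for control replicates 2, 4 and 5 with BDE-209 replicate 1 against the rest, so chance cannot be excluded for the number of lists.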

How the results depend on the processing

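The slide as a random block, quantile normalization without BDE-209 replicate 5 and the probes above the median signal were tests chosen only after the data were seen. Beside 29 changed probes, median scaling gave 45, array weights 50, a trended robust prior 60, the slide as a random block over 7 arrays 49, and only probes above the median signal 75, where fewer probes were tested. limma called 0 without a filter on dim probes (1890 higher and 1021 lower by unadjusted p, with more probes tested), 0 without moderation (1093 and 1673), 0 with the slide as a block (1470 and 931) and 0 with the replicate number as a block (1208 and 922), both over fewer arrays. Leaving out 1 array gave 0 (without BDE-209 replicate 3) to 22 (without BDE-209 replicate 5). Beside 14 gene lists, quantile normalization gave 8, normexp with quantile normalization 9, probes above the median signal 8, fry 4 and an estimated correlation 0 (smallest adjusted p 0.29), and leaving out 1 array 6 to 14. The whole-profile excess was 0.00192 with normexp (exact permutation p = 0.171), 0.00114 without a filter (exact p = 0.171) and 0.00258 under quantile normalization without BDE-209 replicate 5 (exact p = 0.0571), and leaving out 1 array gave -0.000808 to 0.00524. Values with 1 array left out in part reflect unequal numbers of pairs within the 2 groups. Median scaling divides each array by its median signal, which was 33.7 for BDE-209 replicate 5 and 12.9 to 17.1 on the other arrays. It shifts every probe alike and moved the median of all probes to -0.277. This alone put the list medians of monoamine and cholinergic neurotransmission (-0.21), inflammation (-0.136) and skin (-0.03), and cyp1a (-0.12), thrb (-0.248) and mbpa (-0.023), below 0, while camera's direction for the 3 lists stayed higher. hsp70l was above 0 with quantile normalization (0.048), normexp (0.16), the slide as a block (0.087), array weights (0.084), the random slide block (0.13) and quantile normalization without BDE-209 replicate 5 (0.172). dio1 was at -0.029 with normexp, and ttr at 0.311 with the replicate block and 0.002 with array weights. Leaving out 1 array gave -0.163 to 0.143 for hsp70l, -0.041 to 0.069 for thrb and -0.272 to 0.288 for ttr. None of these 6 genes passed the test in any setting. The normexp setting adds an offset of 50 to each intensity, on 7 arrays with median signals of 12.9 to 17.1. By arithmetic alone this draws log2 differences of dim probes towards 0, and its share in the smaller differences under normexp was not measured. Apart from array counts, probe counts, that shift and this offset, no cause was examined. The 14 genes named as changed were chosen for no overlap of the groups. This fixed their direction in advance where an array was left out, the slide or replicate number was a block, arrays were weighted or the prior was changed. In the other settings that measured them, these 14 genes also kept their direction, but not their size. Of these, adamts1 at 0.317, f3b at 0.375 and inhbb at -0.867 with normexp, and stra6 at -0.562 with probes of a gene averaged, shrank by more than 1.5 times, as did klhl43 (0.388), abracl (-0.312) and tm6sf2b (-0.605), which had not passed, with normexp. The shift of median scaling lowers every gene that rose. Over all settings the lowest values were 0.026 for sgk1, 0.199 for ryr3, 0.275 for nr4a2b, 0.344 for dusp1, 0.334 for gadd45ab, 0.416 for aldoab and 0.487 for bhlhe40, among others. Apart from median scaling, genes that the report names as called over their list alone and that shrank by more than 1.5 times included rhcga (0.274), gadd45bb (0.396), atp2a2b (-0.193), zp2.2 (-0.157), cdk1 (-0.361), ldb3b (0.413), gpib (0.384), nherf1a (-0.154), chrna1 (0.266) and guca1g (0.28) with normexp, and nr1d2a (-0.818), chaf1a (-0.285) and zp2.2 (-0.086) with probes averaged. Of called members not named there, srl shrank to 0.341 and 0.247 and ccna2 to -0.339 and -0.039 in these 2 settings, and aurkb to -0.316 with normexp, and the called members that no text names were not all followed through the settings. Normexp also shrank 13 of the 14 list medians by more than 1.5 times, among them cell proliferation to -0.198, retina phototransduction to -0.15 and cholesterol biosynthesis to -0.083, but not that of skeletal muscle. Median scaling ended the camera calls of hypoxia, monoamine and cholinergic neurotransmission, endoplasmic reticulum stress and reference genes. Replicate numbers did not pair the arrays, since deviations of arrays with the same number correlated at -0.066, 0.327 and 0.093 within a range of -0.207 to 0.327, and arrays on 1 slide at 0.228, 0.327 and 0.084. Signal over background limits what can be seen, since 53 to 61.4 percent of probes were well above background on the 7 arrays with flags.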

Other observations

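Tests of single genes named here were chosen only after their values were seen.

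6 genes of regulatory proteins differed without passing limma over all probes. They were picked by their values, and no list of their kind was fixed or tested, so they say nothing about a class of genes. fosb, a further AP-1 subunit, differed by 1.60 ± 0.26 on the log2 scale (SE, n = 4 per group, limma adjusted p = 0.106) and egr2a by 1.77 ± 0.33 (adjusted p = 0.149). egr1 differed by 0.81 ± 0.14, ier2b by 0.82 ± 0.17, junba by 0.74 ± 0.16 and klf2a by 0.67 ± 0.13, with adjusted p of 0.115, 0.18, 0.209 and 0.151. All 6 were higher within slides 1, 2 and 3, fosb by 1.31, 1.28 and 1.59 and egr2a by 1.34, 2.06 and 2.44. With the slide as a block fosb differed by 1.39 and egr2a by 1.95, with adjusted p of 0.441 and 0.502.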
